A study of Homo sapiens with 4 samples.

How the data were processed

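RNA was measured in 4 libraries of HCT116 cells, a human colorectal cancer line, that carry a degron tag on Ki-67. Auxin-type degrons mark the tagged protein for destruction when an auxin such as indole acetic acid (IAA) is added. Per the labels' protocols, each sample came from 3 dishes grown for 2 days, the treated samples received IAA at 0.5 mM for 24 h, mRNA was selected on oligo-dT beads, and paired reads of 150 nt were sequenced. The labels place 2 libraries in the control group and 2 in the IAA group and call them biological replicate samples. They do not say whether equal replicate numbers mark a shared day.

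The authors deposited a single table of 34826 genes with TPM values (read counts divided by gene length and scaled to a sum of 1000000 in each library). The submitters' processing notes name featureCounts 1.5.2, DESeq2 1.20.0 and the builds hg38 and GRCh38.p12, without the role of each. The aligner, its settings and the use of strand in counting are not given in the sources used here. All 34826 gene identifiers, names and start positions matched GENCODE release 29 on GRCh38. The end position in the table differed from that release for 7172 genes, so the coordinates given here are those of the release. A total of 503 rows carried a name found on more than 1 row, and 2347 genes stood at 0 in all 4 libraries.

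The product of TPM and gene length was a whole multiple of a constant step in each library for 100% of genes (tolerance 1e-06), which returned the reads counted per gene. The recovered totals were 38953166 and 49448043 reads for control replicates 1 and 2 and 38733981 and 40920854 reads for IAA replicates 1 and 2. A single read on a gene of 1000 bases was worth between 0.0645 and 0.0853 TPM. Reads without molecular identifiers are not independent molecules, so intervals on read sums (95% exact Poisson) cover counting error only. Pairs of libraries were compared by a chi-square of their recovered reads per gene, over genes with at least 20 reads in the pair, and no pair agreed within sampling noise. No library was therefore counted as a copy of another.

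The comparison of IAA with control was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) on log2(TPM + 1), over 17896 genes with at least 1 TPM in at least 2 libraries, of which 12456 are protein-coding. Fold changes are on that log2(TPM + 1) scale, which understates the change of genes with low values. P-values are two-sided and were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The design has 2 residual degrees of freedom. An exact two-sided permutation test of 2 against 2 libraries cannot give a p below 0.333, so none was used. From 37 gene lists written from textbook knowledge before the data were examined, the 32 with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01 and adjusted over lists. The same lists were tested with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance. An adjusted p over a list alone refers to limma's p-values of its measured members.

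The genes to be named were set by a rule written at the same time. MKI67 and CDKN1A were named in any case. In each direction, up to 10 genes past the threshold were to be named, with places filled to 5 by the smallest p-values among genes with a mean of at least 5 TPM in the higher group and both IAA libraries on the same side of both controls. For the p53, DNA replication, G2 and mitosis and aryl hydrocarbon receptor lists and each list past the threshold, the 2 members with the smallest p in each direction were named. Clone-type names, family-level RNA names and names on more than 1 row were not taken as gene symbols, a reading of the rule made after the data were seen. AHRR, CYP1A1, NQO1, NFE2L2, CD81, CHAC1, TRIB3, PSAT1, ATF4, LSS, FASN, RGS2, DEPP1, BEST1, CLK1, S100A9, KRT13 and CA9 were chosen after their values were seen, as were the squamous epithelium markers.

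The fitting code was tested on simulated data with 200 changed genes drawn on the real means and library sizes. In the simulated IAA against control comparison, over 17873 genes, limma on log2(TPM + 1) recovered 0% of genes changed 1.25-fold, 30% of those changed 1.5-fold, 98% of those changed 2-fold and 100% of those changed 4-fold, with 15 false calls. On 12436 protein-coding genes alone it recovered 32% at 1.25-fold and 98% at 1.5-fold, with 15 false calls. Limma voom on simulated reads recovered 54% at 1.25-fold and 100% at 1.5-fold over 17955 genes, with 13 false calls, and 46% and 100% over 12446 protein-coding genes, with 8. All 4 lists shifted by 0.25 on the log2 scale were recovered among 31 lists tested, with 0 false calls. The simulated genes were independent of each other, so this did not test the correlation between genes of a list. All simulated genes shared a single squared coefficient of variation between replicates (0.00353). The changed genes were drawn only from protein-coding genes with a mean of at least 5 TPM. Real genes need not share a spread, so these shares do not give the power of the real comparison.

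The alternatives set in advance were other pseudocounts, filters, scalings and variance models, the replicate number as a block, each library left out, an estimated correlation and fry. Alternatives added after the data were seen were limma voom on the recovered reads, protein-coding genes alone, both together, both with a mean of at least 500 reads, removal of each library's trend with GC content and gene length, and list members counted without IAA replicate 1. Planned count-based fits applied only if the table held counts and were not run. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No columns of sample values were left unused.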

Results

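The data are poly-A RNA-seq profiles of HCT116 cells in which Ki-67, a nuclear protein of proliferating cells that coats mitotic chromosomes, carries a degron tag. Libraries were made from 2 control samples without treatment and from 2 samples exposed to 0.5 mM indole acetic acid (IAA) for 24 h. The design asks how the transcriptome differs when the tagged protein is degraded. No library of treated cells without the tag was among the samples, so IAA itself and the loss of Ki-67 were present together in every treated library. The libraries held between 38733981 and 49448043 recovered reads. Thinned to 38733981 reads, IAA replicate 1 had the fewest genes detected, 26245 against 26968 to 27448 in the others. Before thinning it had 1787 genes with a single read, against 2776 to 2931. Across genes, which are not independent replicates, the Pearson correlation of log2(TPM + 1) was 0.986 to 0.988 in the 3 pairs with IAA replicate 1 and 0.992 to 0.993 in the other 3. The chi-square per gene was 15.8 between the IAA replicates and 8.12 between the controls. It was 11.9 between control replicate 1 and either IAA library, 14.98 between control replicate 2 and IAA replicate 1, and 5.75 between control replicate 2 and IAA replicate 2, the lowest of the 6 pairs.

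The mRNA of the tagged gene itself was similar in both groups. MKI67 (ENSG00000148773.13, GRCh38 chromosome 10, 128096659 to 128126385, minus strand) had 198 and 151 TPM in control replicates 1 and 2 and 174 and 149 TPM in IAA replicates 1 and 2. The means were 174 ± 32.7 TPM in control and 161 ± 17.8 TPM in IAA (SD, n = 2). The log2 fold change was -0.10 with a standard error of 0.14 and a 95% interval from -0.46 to 0.25, smaller than the spread between the controls (limma adjusted p = 0.999). Its sign was not stable, being 0.09 without control replicate 1 and 0.01 without IAA replicate 2. The degron acts on the protein, so mRNA levels do not check its removal.

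No gene passed the threshold in the comparison of IAA with control. Over 17896 genes limma called 0 higher and 0 lower, with a smallest adjusted p of 0.381. At an unadjusted p under 0.05 there were 742 genes (4.15%), 275 with higher and 467 with lower values in IAA. Both IAA libraries lay above both controls for 11.8% of genes and below both for 17.7%, where chance gives 16.7% each. By limma voom on recovered reads, added after the data were seen, 1 gene was higher and 0 were lower. The counts stayed at 0 without either control. There were 117 higher and 310 lower genes without IAA replicate 1, and 707 and 573 without IAA replicate 2, fits in which the lone IAA library is assumed to vary like the controls.

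The gene called by voom was ALDH1A3, which encodes an aldehyde dehydrogenase that makes retinoic acid (ENSG00000184254.16, chromosome 15, 100877714 to 100916626, plus strand). It had 196 ± 2.63 TPM in control and 302 ± 19.5 TPM in IAA (SD, n = 2), a log2 fold change of 0.62 with a standard error of 0.08. Its adjusted p was 0.381 by limma on log2(TPM + 1) and 0.0120 by voom, and both IAA libraries exceeded both controls. The other genes with the smallest p-values among those higher in both IAA libraries were SNORD14A, RPL38P4, MIR3190 and RNU7-48P, and none passed. SNORD14A, a small nucleolar RNA gene, had 27.6 ± 2.01 TPM in control and 58.0 ± 5.64 TPM in IAA (SD, n = 2). These values rested on 31 and 37 reads in the controls and 67 and 63 in the IAA libraries. RPL38P4 is a processed pseudogene and can share reads with its parent gene, and it had 4.6 ± 0.31 TPM in control and 11.7 ± 0.97 TPM in IAA. MIR3190 rested on 1 and 3 reads in the controls and 8 and 9 in the IAA libraries, and RNU7-48P on 0 reads in both controls and 8 and 3 reads in the IAA libraries.

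Among genes lower in both IAA libraries, CD81-AS1, MT-TA, MIR6835, MIR499B and RNU6-130P had the smallest p-values, and none passed. CD81-AS1, an antisense gene that overlaps CD81, had 10.3 ± 0.04 TPM in control and 4.32 ± 0.62 TPM in IAA (SD, n = 2). Without stated use of strand its reads cannot be separated from those of overlapping genes. CD81 had 81.4 ± 0.13 TPM in control and 77.6 ± 8.50 TPM in IAA (SD, n = 2). The IAA libraries disagreed, with 71.6 TPM in replicate 1 and 83.7 TPM in replicate 2, below and above both controls. MT-TA, the mitochondrial alanine tRNA gene, had 55.7 ± 3.42 TPM in control and 23.0 ± 5.39 TPM in IAA. It rested on 47 and 57 reads in the controls and 22 and 17 in the IAA libraries. MIR6835 had 46.3 TPM in control and 25.9 TPM in IAA, resting on 31 and 51 reads in the controls and 18 and 23 in the IAA libraries. MIR499B and RNU6-130P rested on at most 10 reads in any library. Of the 10 genes named from the extremes of the list, 7 are shorter than a read of 150 nt.

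Of 32 gene lists, 5 passed camera at a preset correlation of 0.01. Genes of the integrated stress response and amino acid synthesis and of cholesterol synthesis were lower in IAA, and aryl hydrocarbon receptor targets, mitochondrially encoded genes and type I interferon response genes were higher. None of the 5 calls held with an estimated correlation, which rests on 2 residual degrees of freedom, and none held by fry. By limma on log2(TPM + 1) no member of any list passed over all genes tested, and by voom ALDH1A3, a member of the aryl hydrocarbon receptor list, did.

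**Figure D1:**
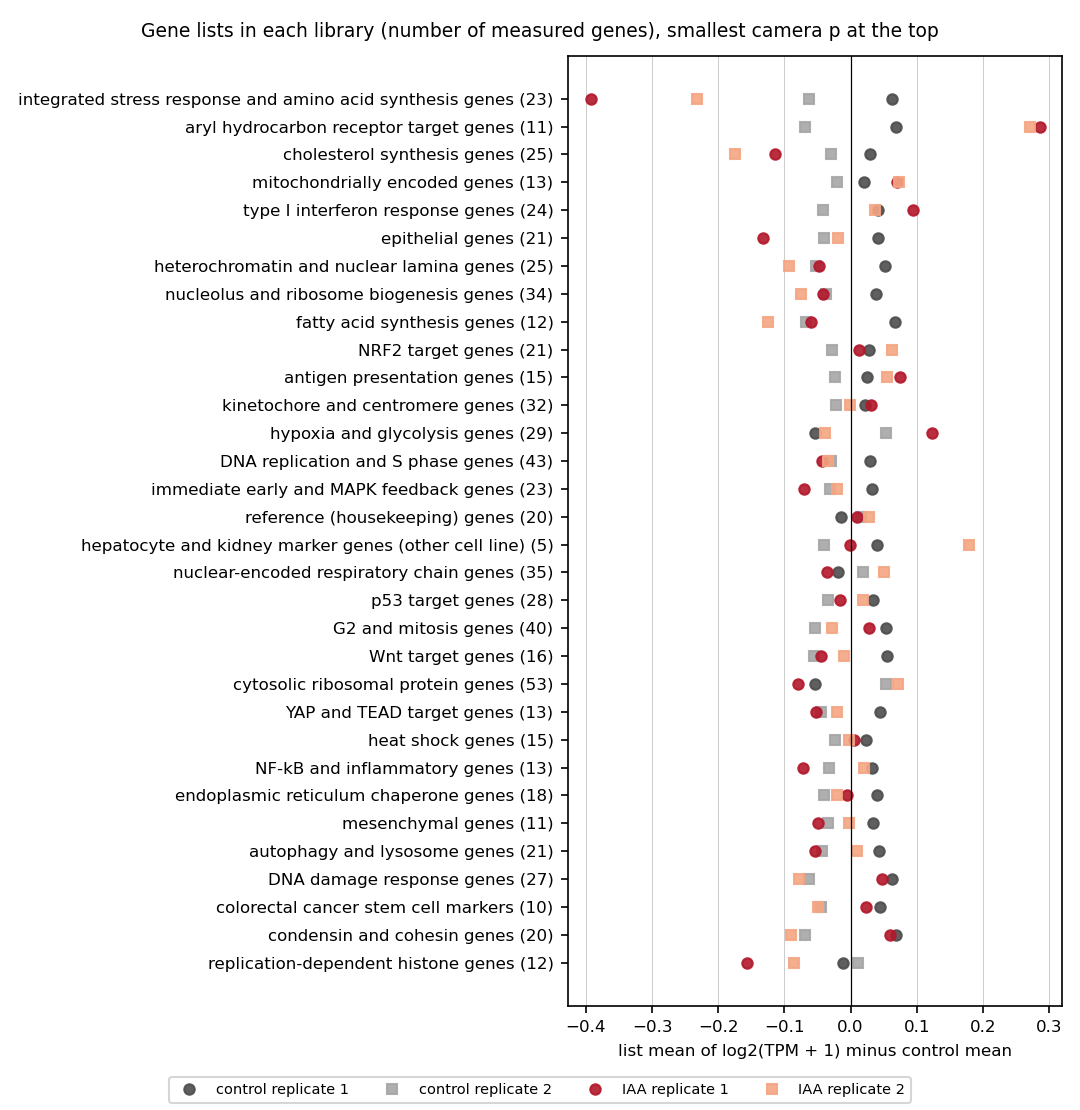
Mean log2(TPM + 1) of each tested gene list in each library, minus the mean of the control libraries, with the number of measured genes in brackets and circles for replicate 1 and squares for replicate 2. The integrated stress response list lies lowest in both IAA libraries, and the aryl hydrocarbon receptor list lies highest, with IAA values 0.20 to 0.35 above single controls.

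Integrated stress response and amino acid synthesis genes, many of them targets of the transcription factor ATF4, were lower as a list, with a median log2 fold change of -0.29 (camera adjusted p = 5.15e-18). The adjusted p was 0.786 with an estimated correlation, which was 0.476 against the preset 0.01, and 0.642 by fry. All 23 measured members had negative fold changes, and 22 lay below both controls in both IAA libraries. Adjusted over the list alone, 4 were lower, DDIT3, DDIT4, TRIB3 and PSAT1, against 0 over all genes tested. DDIT3, which encodes the stress factor CHOP, had 53.1 ± 3.56 TPM in control and 35.7 ± 4.26 TPM in IAA (SD, n = 2), a log2 fold change of -0.56 with a standard error of 0.11. DDIT4, an inhibitor of mTORC1 signalling, had 835 ± 6.42 and 672 ± 1.07 TPM. PSAT1, an enzyme of serine synthesis, had 300.4 ± 9.42 and 226 ± 32.0 TPM, and TRIB3 76.3 ± 1.49 and 53.3 ± 9.83 TPM. The lowest fold change was that of CHAC1 at -0.78 with a standard error of 0.26, at 12.4 TPM in IAA replicate 1 and 22.9 TPM in IAA replicate 2 against 31.4 and 28.3 TPM in the controls. ATF4 itself had 722 ± 3.62 TPM in control and 653 ± 36.2 TPM in IAA. The list means of the IAA libraries differed by 0.16 on the log2 scale, IAA replicate 1 being the lower. Without that library the list median was -0.235.

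Aryl hydrocarbon receptor target genes were higher as a list, with a median log2 fold change of 0.27 (camera adjusted p = 1.07e-08). The adjusted p was 0.786 with an estimated correlation and 0.555 by fry. Of 11 measured members, 10 had positive fold changes and 9 lay above both controls in both IAA libraries. Adjusted over the list alone, 5 were higher (ALDH1A3, TIPARP, NQO1, AHRR and NFE2L2) and SLC7A5 was lower, against 0 over all genes tested by limma on log2(TPM + 1) and ALDH1A3 alone by voom. TIPARP, an ADP-ribosyltransferase that restrains the receptor, had 28.4 ± 1.82 TPM in control and 39.7 ± 4.0 TPM in IAA (SD, n = 2), a log2 fold change of 0.47 with a standard error of 0.10. AHRR, the receptor's repressor, had 3.81 ± 0.80 and 6.21 ± 0.01 TPM, and NQO1, a quinone reductase also induced by NRF2, had 367 ± 5.46 and 444 ± 4.36 TPM. CYP1A1, the classical target, stayed low at 2.36 ± 1.02 TPM in control and 3.98 ± 0.40 TPM in IAA. SLC7A5, an amino acid transporter gene that is also in the stress response list, had 304 ± 30.1 and 233 ± 29.9 TPM.

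**Figure D2:**
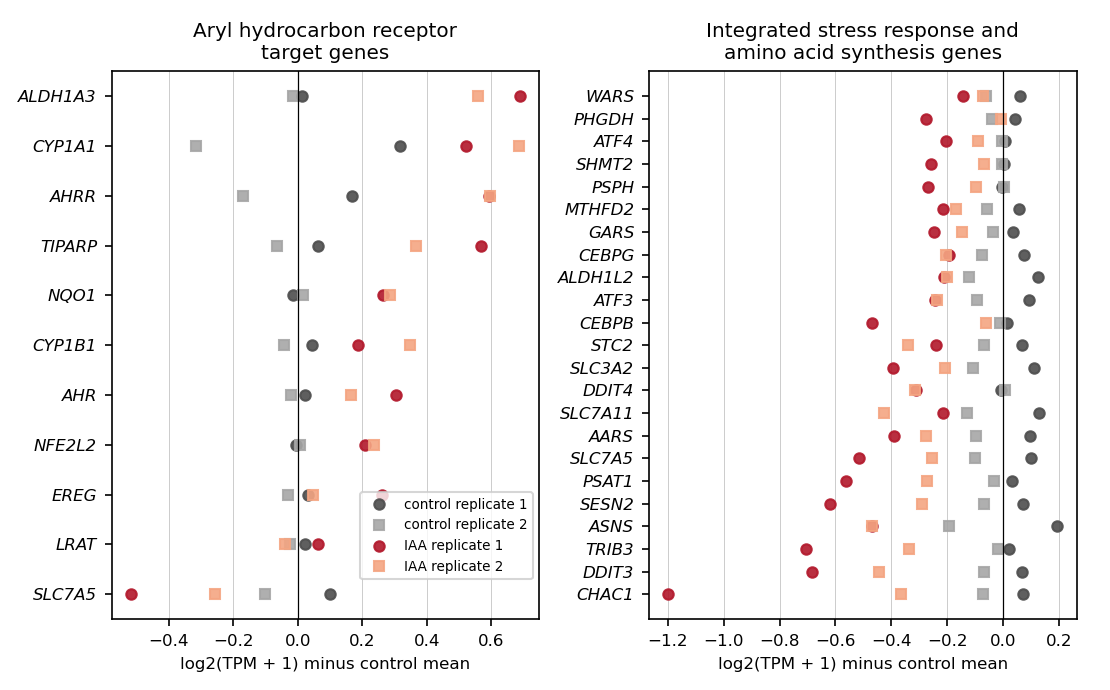
Log2(TPM + 1) of each measured aryl hydrocarbon receptor target gene (left) and integrated stress response or amino acid synthesis gene (right) in each library, minus the mean of the controls, with circles for replicate 1 and squares for replicate 2. On the left, 9 of 11 genes lie above both controls in both IAA libraries, and on the right 22 of 23 lie below both.

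Cholesterol synthesis genes were lower as a list by a smaller amount, with a median log2 fold change of -0.14 (camera adjusted p = 2.65e-08). The adjusted p was 0.786 with an estimated correlation and 0.555 by fry. All 25 members had negative fold changes and 15 lay below both controls in both IAA libraries. Adjusted over the list alone, 0 members passed. MVD, an enzyme of the mevalonate pathway, had 86.4 ± 1.85 TPM in control and 71.4 ± 0.95 TPM in IAA (SD, n = 2). CYP51A1, lanosterol demethylase, had 21.05 ± 2.70 and 15.4 ± 0.22 TPM, and LSS, lanosterol synthase, 61.4 ± 4.56 and 51.6 ± 0.69 TPM.

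Mitochondrially encoded genes and type I interferon response genes passed camera with small shifts. The 13 mitochondrially encoded mRNAs had a median log2 fold change of 0.08 (camera adjusted p = 0.0158, and adjusted p = 0.786 with an estimated correlation), with 12 positive and 0 passing adjusted over the list alone. MT-CO3 had 24558 ± 1565 TPM in control and 27456 ± 702 TPM in IAA (SD, n = 2), MT-ND4 12880 ± 313 and 14170 ± 547 TPM, and MT-ATP8 3845 ± 316 and 3628 ± 290 TPM. The interferon list of 24 measured genes had a median of 0.06 (camera adjusted p = 0.0198, and adjusted p = 0.969 with an estimated correlation), with 18 positive, 6 negative and 0 passing adjusted over the list alone. BST2 had 10.2 ± 1.21 and 14.1 ± 0.04 TPM, IFIT1 10.9 ± 0.01 and 13.1 ± 1.04 TPM, IRF9 2.83 ± 0.23 and 1.84 ± 0.37 TPM, and IFI35 25.3 ± 0.20 and 24.6 ± 0.39 TPM. The mitochondrial call ended without control replicate 1, control replicate 2 or IAA replicate 2 (camera adjusted p = 0.331, 0.124 and 0.438) and with TMM factors (0.329). The interferon call ended without control replicate 2, IAA replicate 1 or IAA replicate 2 (0.0826, 0.0576 and 0.508).

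Cell cycle and p53 lists, the programs nearest to the role of Ki-67 as a proliferation marker, did not pass. The 28 measured p53 target genes had a median log2 fold change of 0.01 (camera adjusted p = 0.516), with 15 positive and 13 negative. CDKN1A, which encodes the cell cycle inhibitor p21, had 251 and 244 TPM in the controls and 225 and 254 TPM in IAA replicates 1 and 2, a log2 fold change of -0.05 with a 95% interval from -0.26 to 0.15, and of 0.04 without IAA replicate 1. PLK2 had 28.95 ± 0.43 TPM in control and 32.9 ± 0.50 TPM in IAA (SD, n = 2), TRIAP1 69.7 ± 0.60 and 76.3 ± 0.06 TPM, PLK3 31.5 ± 2.44 and 28.0 ± 2.08 TPM, and SESN2, which is also in the stress response list, 29.6 ± 2.08 and 21.4 ± 3.61 TPM. The 43 DNA replication and S phase genes had a median of -0.04 (camera adjusted p = 0.276). Among them RRM2 had 84.1 ± 3.84 and 93.3 ± 2.21 TPM, CCNE2 6.90 ± 0.49 and 8.14 ± 1.10 TPM, UHRF1 63.0 ± 5.98 and 53.2 ± 0.54 TPM, and CDT1 116 ± 1.17 and 99.8 ± 11.03 TPM. The 40 G2 and mitosis genes had a median of 0.01 (camera adjusted p = 0.516). CCNA2 had 150.05 ± 1.92 and 164 ± 11.1 TPM, KIF23 67.1 ± 2.37 and 71.3 ± 3.90 TPM, INCENP 87.1 ± 10.4 and 78.6 ± 0.73 TPM, and AURKB 119 ± 2.14 and 113 ± 10.3 TPM. In these 3 lists 0 members passed adjusted over the list alone.

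The remaining lists did not pass either. Across all 27 lists that missed the threshold the median log2 fold changes lay between -0.08 and 0.09 and the camera adjusted p between 0.0677 and 0.949. Epithelial genes (median -0.08, camera adjusted p = 0.0677) and heterochromatin and nuclear lamina genes (median -0.06, camera adjusted p = 0.0677) came nearest, followed by nucleolus and ribosome biogenesis genes (median -0.06, camera adjusted p = 0.0828). The heterochromatin and lamina list passed by voom and without control replicate 2, and the epithelial list without IAA replicate 2. Kinetochore and centromere genes had a median of 0.02, condensin and cohesin genes of -0.01 and housekeeping genes of 0.01. The sign of the camera test differed from that of the list's median or mean for nuclear-encoded respiratory chain, cytosolic ribosomal protein, heat shock, endoplasmic reticulum chaperone, autophagy, DNA damage response and replication-dependent histone genes, all of which missed the threshold.

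Markers of other cell types were given as summed reads where fewer than 5 of a kind were measured. Blood cell markers summed to 10.8 reads per 1000000 in both controls, 8.65 in IAA replicate 1 and 10.4 in IAA replicate 2, so that both IAA libraries lay below both controls. Endothelial markers summed to 67.2 and 72.0 reads per 1000000 in the controls and to 62.2 and 75.8 in IAA replicates 1 and 2, and neuronal markers to 44.6 and 41.6 against 50.2 and 44.1. Fibroblast markers summed to 233 and 223 against 213 and 218, again with both IAA libraries below both controls. Intestinal differentiation genes summed to 55.8 and 58.5 reads per 1000000 in the controls and 57.6 and 61.3 in the IAA libraries. Hepatocyte and kidney markers, 5 of them measured, had a median log2 fold change of 0.04 (camera adjusted p = 0.378). Genes of squamous epithelium, picked after their values were seen, included several with higher values in IAA replicate 1 than in the other libraries, while KRT14 and KRT6A were near the level of a control there. S100A9, a calcium-binding protein of neutrophils and squamous epithelium, had 15.5 TPM there against 1.63, 1.79 and 0.68 TPM in control replicates 1 and 2 and IAA replicate 2. KRT13, a keratin of stratified epithelium, had 6.73 TPM there against 2.31, 2.19 and 2.36 TPM.

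**Figure D3:**
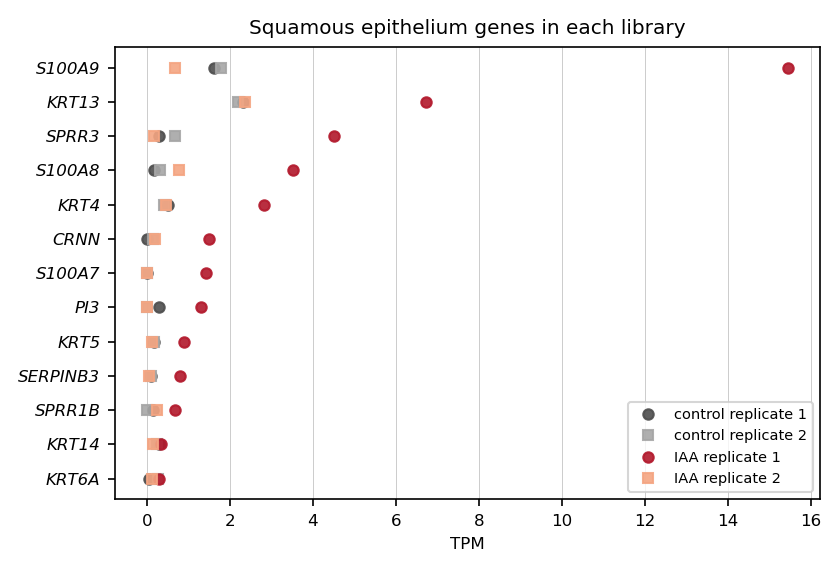
TPM of 13 genes of squamous epithelium in each library, with circles for replicate 1 and squares for replicate 2. The set was chosen after high values of some of its genes in IAA replicate 1 were seen, with S100A9 at 15.5 TPM in that library and at most 1.79 TPM in the others.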

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

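Alternatives using voom, protein-coding genes alone, a mean of at least 500 reads, or removal of the GC content and length trend were chosen after the data were seen, as were the counts of list members without IAA replicate 1. Across the alternatives set in advance that kept the 4 libraries, limma called 0 genes in each direction. Voom called 1 higher and 0 lower gene, on all genes, on protein-coding genes and on those with a mean of at least 500 reads. In each case it was ALDH1A3, with an adjusted p from 0.00295 to 0.0120. With limma on protein-coding genes alone, 12 genes were higher and 25 lower. Its estimate of the prior degrees of freedom became infinite there, so that every gene took the trend's variance, and S100A9 and KRT13, high in 1 library, were among the calls. Leaving out a library gave 0 to 707 higher and 0 to 573 lower genes and an infinite prior without either IAA library.

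Aryl hydrocarbon receptor, integrated stress response and cholesterol synthesis lists kept their direction and their call at the preset correlation under every scaling, pseudocount, filter and left-out library tried. With the correlation estimated from the data 0 lists passed, and by fry 0. The medians are then as before (0.27, -0.29, -0.14, 0.081 and 0.063 for the aryl hydrocarbon receptor, stress response, cholesterol, mitochondrial and interferon lists), with an adjusted p from 0.786 to 0.969 with the estimated correlation and from 0.555 to 0.835 by fry. Fewer residual degrees of freedom (2) enter those tests than camera uses at a preset correlation. The number of lists past the threshold was 3 with no filter, 5 to 8 with a library left out, 11 on protein-coding genes, and by voom 10 on protein-coding genes and 8 on those with a mean of at least 500 reads. Among lists that missed the threshold in the report, heterochromatin and nuclear lamina genes passed in all 3 voom fits, on protein-coding genes with limma, with the GC content and length trend removed and without control replicate 2, and epithelial genes on protein-coding genes by limma and voom and without IAA replicate 2. NRF2 target, antigen presentation and nuclear-encoded respiratory chain genes also passed in some fits. Cytosolic ribosomal protein genes, with a median of -0.0008 over all libraries, passed in every fit with a library left out. Passing with a library left out therefore says little on its own. The mitochondrial list missed the threshold with no filter (median 0.081), TMM factors (0.090), median-of-ratios factors (0.095), quantile normalization (0.057) and the GC content and length trend removed (0.031), and with libraries left out its median ranged from 0.082 to 0.090 where the call ended. The interferon list missed it with no filter (0.052) and ranged from 0.029 to 0.117 with libraries left out where the call ended. The cause was not tested. Cholesterol genes below both controls numbered 15 in both IAA libraries and 23 without IAA replicate 1, a looser criterion that cannot give a lower count and so tests nothing.

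Most directions that reversed belonged to values near 0. With a library left out, the log2 fold change of MKI67 ranged from -0.294 to 0.089 (above 0 without control replicate 1 or IAA replicate 2), of MT-ATP8 from -0.168 to 0.000305 (above 0 without control replicate 1), of CDKN1A from -0.140 to 0.036 and of AURKB from -0.173 to 0.011 (both above 0 without IAA replicate 1). CD81 ranged from -0.182 to 0.0385, above 0 without IAA replicate 1, and was 0.0364 with the GC content and length trend removed. S100A9 is the exception, from -0.691 without IAA replicate 1, the library that set its value, to 2.61. The list medians ranged from -0.016 to 0.056 for p53 targets, where the test turned without IAA replicate 2 (median -0.014), from -0.041 without control replicate 2 to 0.053 for G2 and mitosis, and from -0.061 to -0.016 for S phase, where the test turned without IAA replicate 1 (median -0.032). With the replicate number as a block, limma called 0 genes in each direction and 5 lists, so the block changed no call. The labels do not say that the numbers pair the libraries, and the differences between replicates 1 and 2 of both groups had a correlation of -0.069 across genes. For named genes 915 values kept direction and side of the threshold, 62 newly passed and 6 reversed. Depth limits small RNAs most, since a single read on 1000 bases is worth up to 0.0853 TPM and more on shorter genes. Robust variance estimation does not enter camera, so it gave no list value.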

Other observations

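The tests of single libraries and of the spread within a group were chosen after the results were seen, as was the comparison of splits. The genes in the next paragraph were chosen after their values were seen.

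Several protein-coding genes not named so far had both IAA libraries on the same side of both controls without passing the limma threshold over all genes. RGS2, a regulator of G protein signalling, had 38.3 ± 0.40 TPM in control and 52.2 ± 2.21 TPM in IAA (SD, n = 2). DEPP1 had 13.5 ± 1.69 and 19.8 ± 1.38 TPM, and BEST1, a chloride channel gene, 19.0 ± 0.51 and 28.1 ± 7.04 TPM. CA9, a carbonic anhydrase of the hypoxia and glycolysis list, had 2.46 ± 0.45 and 4.30 ± 0.40 TPM. Lower values were seen for CLK1, a kinase of splicing factors, with 31.3 ± 1.60 and 22.8 ± 3.44 TPM, and for FASN, fatty acid synthase and a member of the fatty acid synthesis list, with 368 ± 46.2 and 283 ± 6.5 TPM. Their limma adjusted p over all genes lay between 0.682 for RGS2 and 0.999 for BEST1, and the camera tests of these lists on log2(TPM + 1) with all 4 libraries and all genes did not pass. The fatty acid list did pass by voom, and both passed in some fits with a library left out. With protein-coding genes alone all 6 passed by limma, in a fit with an infinite prior that also called S100A9 and KRT13, high in 1 library, and 0 of the 6 passed by voom, which called ALDH1A3 alone.

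Aryl hydrocarbon receptor targets were higher in IAA as a list at the preset correlation only (adjusted p = 0.786 with an estimated correlation and 0.555 by fry). Without IAA replicate 1 the list passed at that setting (camera adjusted p = 1.78e-07). That pass decides little, because the fit holds a single IAA library. It also called the cytosolic ribosomal protein list, whose median was -0.0008 over all libraries. The sizes say more, since the list median stayed between 0.229 and 0.285 with each library left out in turn. These medians argue against any single library as the whole cause. A trend with GC content and gene length is also argued against, because the list median was 0.27 before and 0.2675 after each library's trend was removed. Indole compounds include ligands of this receptor, so a candidate explanation is that IAA acts on the receptor apart from the loss of Ki-67. It cannot be told apart from an effect of Ki-67 loss, because there were 0 libraries of IAA-treated cells without the degron tag.

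Integrated stress response genes were lower in IAA as a list at the preset correlation only (adjusted p = 0.786 with an estimated correlation and 0.642 by fry). At that setting the list passed without IAA replicate 1 (camera adjusted p = 5.64e-10). This pass decides little, because that fit holds a single IAA library and also called the cytosolic ribosomal protein list. The stress response median stayed between -0.331 and -0.192 with each library left out in turn. It was -0.24 after removal of the GC content and length trend. These medians argue against a single library and against that trend as the whole cause. The list means differed by 0.160 between the IAA replicates and by 0.126 between the controls on the log2 scale, against a group difference of -0.31. For the nearest IAA and control libraries, the difference of IAA from control was -0.169. The split that set control replicate 1 and IAA replicate 2 against the other libraries also called the list (camera adjusted p = 0.00645). Variation between cultures of one group may therefore contribute, and an effect of the treatment stays open beside it.

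Squamous epithelium genes as a set stood out in IAA replicate 1, where 13 markers noticed first summed to 18.3 reads per 1000000 against 3.59 to 3.94 in the other libraries. Of 30 further markers detected and under 5 TPM in both controls, 16 were highest in that library (25% by chance), with 11.2 reads per 1000000 in sum (95% interval 10.2 to 12.3) against 7.60 to 8.42. In IAA replicate 2 the markers noticed first summed to 3.64, between the controls, and the further markers to 7.60, below both controls. These sums argue against a rise shared by both treated libraries. Only 6 of the 30 were higher in IAA replicate 2 than in both controls, but many had a few reads per library, so that count alone decides little. A candidate source is RNA of squamous epithelium in that library, whether from handling or from another sample read in the same run. Blood cells as the source of S100A8 and S100A9 stay open, since their markers summed to 8.65 reads per 1000000 in that library, below the other libraries, over a baseline that would hide a small share.

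Of the 3 splits of the 4 libraries into pairs, 2 called at least as many lists as the real 5, the real one included, and the highest other count was 5. With 3 splits no share under 0.05 can be reached. The other splits did not call the aryl hydrocarbon receptor list (camera adjusted p = 0.907 and 0.871) or the cholesterol list (0.907 and 0.773). Both lists were picked because they passed in the real split, so these misses give no support. The split that set control replicate 1 and IAA replicate 1 against the other libraries called 5 lists. They were condensin and cohesin, cytosolic ribosomal protein, DNA damage response, nuclear-encoded respiratory chain and housekeeping genes. None of them was called in the real split.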
